A study of Mus musculus with 4 samples.

How the data were processed

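RNA of 4 mouse samples was measured on Illumina bead arrays, 1 array per sample. The labels give the TRAMP prostate tumor cell lines T23 and T1525, 1 array each at 30 weeks of age, and normal prostate of C57Bl/6 mice, 2 arrays at 18 weeks. The labels say nothing of separate cultures of a line, nor whether the 2 normal arrays came from separate mice, so the SDs and p-values measure only the spread between these arrays, which may leave out the spread between mice, and a difference of a single line has no replicate check. Age, culture and tumor go together with the group.

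The values used were the deposited normalized intensities of 24613 probes on a linear scale. BeadStudio is named in the submitters' processing notes; its version and the method of normalization are not given in the sources used here. The 4 columns of deposited intensities held nearly the same sorted values, with a median gap of 0.183% and a largest gap of 3.73%, as after quantile normalization by the authors, and showed no sign of background subtraction. The median intensity was 105.5 in both lines and 106.2 and 106.3 in the normal samples. A table of signals before normalization and detection p-values has 8 columns of per-sample values named by slide position only, which cannot be tied to samples by their labels; these were not used here, and slides were not used as a block.

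The design fixed before the data were examined called for background correction from those signals and a filter on detection p-values, which these values do not allow. Instead the log2 of the deposited intensity was taken, and a background threshold was estimated after the values were seen. It was the mode of the log2 intensities (6.12) plus the one-sided 0.01 tail of a normal distribution with the SD of the values left of the mode (0.247), which gave 6.69, an intensity of 103. Probes above it on at least 1 array were kept (15767), and 12502, 12499, 12550 and 12563 probes lay above it in T23, T1525, normal 1 and normal 2. Gene symbols came from the platform's probe table: 20984 probes had 1 symbol, 1 had several and 3628 had none given. Of the symbols, 20968 were found by Entrez ID in the RefSeq table of mouse build GRCm38.p6, and 0 changed. A gene with several kept probes was represented by the one with the highest mean; of 2221 such genes, 0 had probes called in opposite directions and 281 had a called and an uncalled probe. Where an array lay at or below background its value was set to the threshold before a fold or a difference of a named gene was taken, and the result is given as at least that much. Fitted differences and list medians use the values as measured unless stated. A p-value printed beside an at-least value belongs to the fitted difference and does not test the bound.

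Differences were tested with limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05. The 2 lines were compared with the 2 normal samples as classes, with 2 residual degrees of freedom and 2.07 prior degrees of freedom. Each line was compared with normal prostate in a fit of 3 groups, with 1 residual degree of freedom, 2.95 prior degrees of freedom and the line assumed to vary like the normal samples. T23 and T1525 were compared without a test, by the log2 difference of single arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

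There were 23 gene lists fixed before the data were examined: prostate secretory products, luminal regulators, seminal vesicle secretions, epithelial adhesion and keratins, basal epithelium, mesenchymal genes, matrix proteases and inhibitors, neuroendocrine genes, mast cell genes, mast cell attracting and growth factors, cell cycle and E2F targets, p53 pathway targets, smooth muscle, fibroblast and matrix, endothelium, leukocytes, skeletal muscle, adipose, blood, MHC class I presentation, interferon-stimulated genes, glycolysis and hypoxia, and stem-like genes. Cd44, Perp and Vegfa stand in 2 lists each. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists. With an estimated correlation camera works on the 2 residual degrees of freedom of the class fit, so few lists could pass it. Between the lines, a list's median difference was placed among 10000 random lists of the same size matched on mean expression, and called outside the central range in the outer 2.5% on either side.

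Genes were named by a rule fixed before the data were examined. It took the 10 largest changes in each direction past the threshold with both lines on the same side of both normal samples, the 10 largest differences in each direction between the lines, up to 4 members per list by the class difference and up to 2 by the difference between lines, and 18 fixed genes. Of the fixed genes 13 had a kept probe, and the others are not reported here. This gave 147 genes.

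The fits were tested on simulated data with 200 changed probes in 10 simulations. With variances drawn from the fitted prior, the class fit recovered 0.6%, 58.6% and 82.8% of changes of 2, 4 and 6 on the log2 scale, with 2.81% false calls. With each probe's fitted variance, a scheme added after the first result was seen, it recovered 21.8%, 89% and 97.2%, with 7.74% false calls. Changes of 1 were recovered in 0% of cases under both schemes. The fits of the real data called far more than 200 probes. The shares of recovered changes and of false calls depend on how many probes change. These rates therefore describe the simulations and do not carry over to the real calls.

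Alternatives fixed before the data were examined were median scaling, cyclic loess, no filter on dim probes, the background threshold on at least 2 arrays, a looser tail of 0.05, leaving out each array, another variance model, a 2-fold minimum, the spread of the normal samples alone, a log2 difference of 1 between lines, and other list tests. Normexp background correction with an offset of 50 and a stricter tail of 1e-04 were chosen after the data were seen. So were the analysis of chromosomes and its minimum of expression, the search for neighbouring genes at background, the tests of ranks within arrays, the values set to the threshold array by array and their folds without each array, the placing of the normal pair among random lists, and the Hox genes described in the closing section.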

Results

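Gene expression was measured on 4 Illumina bead arrays of mouse RNA. TRAMP mice carry a transgene that drives SV40 tumor antigens in the prostate epithelium and develop prostate tumors. T23 and T1525 are cell lines from prostate tumors of such mice, taken at 30 weeks of age, with 1 array each. Normal prostate of C57Bl/6 mice at 18 weeks of age gave 2 arrays, called normal 1 and normal 2; the labels do not say whether these came from separate mice. The lines and the normal tissue therefore differed in age and in being grown in culture as well as in the tumor, and these cannot be told apart here. Of 24613 probes, 15767 lay above the background threshold on at least 1 array and represented 10903 named genes. Between 50.8% and 51.0% of the probes lay above that threshold on each array, and the number of arrays limits the precision. Across the kept probes, which are not independent replicates, log2 intensities of the normal pair correlated with r = 0.963, those of T23 and T1525 with r = 0.837, and those of a line and a normal sample with r between 0.719 and 0.753.

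The series asks how prostate tumor cell lines differ from normal prostate. Genes of cell division were higher in both lines, and the secreted proteins of prostate and seminal vesicle were at background in most cases. Birc5, an inhibitor of apoptosis that acts in mitosis, was 12.70 ± 0.04 (SD, n = 2) in the lines and 7.82 ± 0.18 (SD, n = 2) in normal prostate on the log2 scale, a 29.5-fold rise (limma, SE 0.23, adjusted p = 0.00898). Tgm4, the prostate transglutaminase, was 15.72 ± 0.04 (SD, n = 2) in normal prostate and not above background in either line, at least 522-fold lower (limma, SE 0.22, adjusted p = 0.00542). Myh11, the smooth muscle myosin heavy chain, was at least 218-fold lower in the lines (limma, adjusted p = 0.00542). Of 59 genes of smooth and skeletal muscle, fat, blood, endothelium and leukocytes, limma called 37 lower in the lines. With an estimated correlation 0 of these 6 lists passed camera, which few lists could pass with 2 residual degrees of freedom. The normal samples were tissue and the lines were cultured cells. For these 59 genes and those of seminal vesicle, lower expression within a cell cannot be told apart from absence of those cells in the lines.

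In limma's comparison of the 2 lines with the 2 normal samples, 1698 of 15767 probes changed, 889 higher and 809 lower in the lines, which left 578 genes higher and 664 lower among 10903. The split depended on the scaling: 36.4% of the calls were higher with median scaling and 36.3% with cyclic loess, against 52.4% with the deposited values, while the median difference over all probes moved from 0.19 to -0.05 and -0.02 on the log2 scale. Without normal 1 or without normal 2 limma called 0 probes, with 2507 and 2266 probes at an unadjusted p under 0.05 against 4990 with all arrays; without T23 it called 4823 and without T1525 4578.

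By the fitted difference, the 10 genes with the largest rise past the threshold were H2ac12, Birc5, Plk1, Aurkb, Cenpa, Shcbp1, Spag5, Cdk1, Tpx2 and Cep55. H2ac12, a histone H2A gene, was 34.9-fold higher (log2 difference 5.13, SE 0.62, adjusted p = 0.0266). Cenpa, the centromeric histone H3 variant, was 22.9-fold higher (log2 difference 4.52, SE 0.27, adjusted p = 0.011). Tpx2, a spindle assembly factor, was 20.1-fold higher. Shcbp1 and Cep55 were not above background in normal prostate and were at least 15.8-fold and at least 13.5-fold higher in the lines. Ordered with values at background set to the threshold, 8 of the 10 stayed among the 10 largest, without Shcbp1 and Cep55. Without T23 and without T1525, H2ac12 was 60.8-fold and 20.1-fold higher and Tpx2 34.8-fold and 11.6-fold.

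By the fitted difference, the 10 genes with the largest fall were Svs4, 9530002B09Rik, Tgm4, Defb50, 9530003J23Rik, Svs2, Msmb, Acta1, Myh11 and Svs5. Svs4, a seminal vesicle secretory protein, was at least 481-fold lower (fitted log2 difference -9.48, SE 0.24, adjusted p = 0.00542). Defb50, a beta-defensin, was at least 396-fold lower, and Msmb, the prostate secretory protein beta-microseminoprotein, at least 403-fold lower. Acta1, the skeletal muscle actin, was at least 323-fold lower. Most of these genes lay at background in the lines, so their order is not resolved. With values at background set to the threshold Tgm4 came first, and 9 of the 10 stayed among the 10 largest, with Hba-a1 in place of Myh11.

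**Figure D1:**
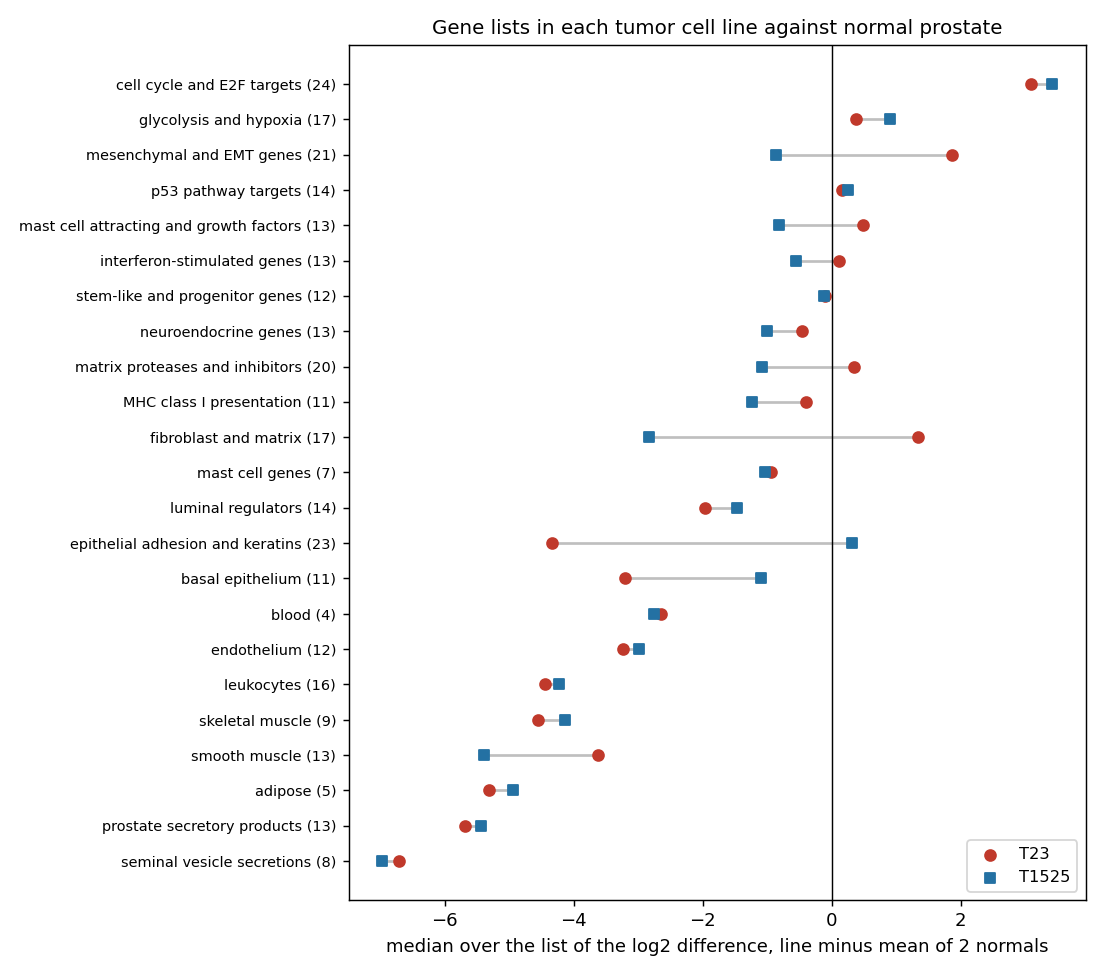
Median log2 difference from the mean of the 2 normal samples (horizontal axis, log2) over each of 23 gene lists, for T23 (circles) and T1525 (squares), with the number of genes measured in brackets and a grey line joining the lines. The medians of the cell cycle list were 3.09 and 3.42, while those of the epithelial list were -4.33 in T23 and 0.31 in T1525; with values at background set to the threshold the epithelial median in T23 was -3.61.

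The cell cycle and E2F target list moved most uniformly upward. Of its 24 measured genes, 23 rose over all genes tested and 24 when adjusted over the list alone, with a median log2 difference of 3.19. Plk1, a mitotic kinase, rose 26.0-fold (adjusted p = 0.0118), Aurkb, a kinase of the chromosomal passenger complex, rose by 4.52 on the log2 scale and Cdk1, the mitotic cyclin-dependent kinase, rose 20.9-fold. Pcna, the DNA polymerase clamp, rose 6.44-fold, 9.76-fold without T23 and 4.25-fold without T1525. Ube2c, a ubiquitin-conjugating enzyme of mitosis, was the gene short of the threshold over all genes, at a fitted log2 difference of 2.52 (adjusted p = 0.0516). The list passed camera at adjusted p = 4.45e-16, and adjusted p = 0.242 with an estimated correlation.

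Of 13 prostate secretory genes, 9 fell over all genes and 11 when adjusted over the list alone, with a median log2 difference of -5.45 (camera adjusted p = 4.06e-09; adjusted p = 0.242 with an estimated correlation). Pbsn, the androgen-dependent secretory protein probasin whose promoter drives the TRAMP transgene, was at least 18.2-fold lower, Spink1 at least 185-fold lower and Apof at least 43.3-fold lower. For Spink1 the bound was 79.2-fold without normal 1 and 431-fold without normal 2. Sbpl read 15.70 in normal 1 and 11.29 in normal 2, and its fitted difference of -7.30 did not pass (adjusted p = 0.0635). Of 8 seminal vesicle genes, 7 fell over all genes and 8 when adjusted over the list alone, with a median of -6.84 (camera adjusted p = 2.08e-08; adjusted p = 0.242 with an estimated correlation). Svs2 was at least 403-fold lower, Svs5 at least 332-fold and Svs3b at least 159-fold.

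Among 14 luminal regulators, 4 fell over all genes and 6 when adjusted over the list alone, with a median of -1.44 (camera adjusted p = 0.00222; adjusted p = 0.242 with an estimated correlation). Hoxb13, a homeobox factor of the prostate, was at least 61.0-fold lower (fitted log2 difference -6.28, SE 0.62, adjusted p = 0.0199), and Tmprss2, an androgen-regulated serine protease, at least 42.7-fold lower (adjusted p = 0.0304). The bound for Hoxb13 was 40.5-fold without normal 1 and 91.8-fold without normal 2, and that for Tmprss2 23.9-fold without T23 and 76.3-fold without T1525. Foxa1, a pioneer factor of luminal cells, read 6.26 in T23, 10.62 in T1525, 12.74 in normal 1 and 12.18 in normal 2. Of 11 basal epithelial genes, 3 fell over all genes and 5 when adjusted over the list alone, with a median of -1.92 (camera adjusted p = 0.00222; adjusted p = 0.431 with an estimated correlation). Krt15 was at least 34.8-fold lower and Krt5 at least 9.53-fold lower, and Trp63, the basal cell transcription factor p63, missed the threshold at a fitted difference of -4.29 (adjusted p = 0.0507). Without T23, T1525, normal 1 and normal 2 the bound for Krt15 was 21.9-fold, 55.4-fold, 55.0-fold and 22.0-fold, and without normal 1 and normal 2 that for Krt5 was 15.7-fold and 5.79-fold. The camera call of the basal list ended without T23 (median -1.10, adjusted p = 0.0966), and without T1525 the median was -3.20, with adjusted p between 3.81e-05 and 0.0966 over 12 alternatives.

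Of 13 smooth muscle genes, 10 fell over all genes and 11 when adjusted over the list alone, with a median of -4.89 (camera adjusted p = 3.35e-09; adjusted p = 0.242 with an estimated correlation). Actg2, the enteric smooth muscle actin, was at least 280-fold lower and Mylk, the myosin light chain kinase, at least 197-fold lower; for Actg2 the bound was 457-fold without T23 and 172-fold without T1525. Of 9 skeletal muscle genes, 8 fell over all genes and 9 when adjusted over the list alone, with a median of -4.35 (camera adjusted p = 1.58e-09; adjusted p = 0.242 with an estimated correlation), and Atp2a1, the muscle calcium pump, was at least 90.3-fold lower. Of 5 adipose genes, 3 fell over all genes and 5 when adjusted over the list alone, with a median of -5.13 (camera adjusted p = 0.000539; adjusted p = 0.242 with an estimated correlation), and Adipoq, the fat cell hormone adiponectin, was at least 49.8-fold lower, 82.4-fold without normal 1 and 30.1-fold without normal 2. The adipose median was -1.48 with no filter on dim probes and -3.31 with a looser background tail. Of 4 blood genes, 3 fell over all genes and 3 when adjusted over the list alone, with a median of -2.70 (camera adjusted p = 0.00128; adjusted p = 0.352 with an estimated correlation), and the globin gene Hba-a1 fell 303-fold. Hba-a1 read 6.72 in T23 and 6.87 in T1525, just above the background threshold of 6.69, so background limits its fold.

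Of 16 leukocyte genes, 7 fell over all genes and 12 when adjusted over the list alone, with a median of -4.34 (camera adjusted p = 5.00e-08; adjusted p = 0.461 with an estimated correlation). Cd74, the invariant chain of MHC class II, was at least 71.0-fold lower and Laptm5 at least 69.4-fold lower in the lines. Without normal 1 and normal 2 these bounds were 148-fold and 34.1-fold for Cd74 and 147-fold and 32.7-fold for Laptm5. All 16 leukocyte genes were higher in normal 2 than in normal 1, by a median of 2.07 on the log2 scale, and at most 1 of them lay above background in either line. Of 12 endothelial genes, 6 fell over all genes and 10 when adjusted over the list alone, with a median of -3.18 (camera adjusted p = 8.28e-06; adjusted p = 0.441 with an estimated correlation). Emcn was at least 24.9-fold lower, Esam at least 20.5-fold lower, and Vwf, von Willebrand factor, fell 17.8-fold, while Kdr, a receptor of vascular endothelial growth factor, rose in T1525 by at least 0.999 (adjusted p = 0.0319). Without normal 1 and normal 2, Esam was at least 33.1-fold and at least 12.7-fold lower and Vwf 34.4-fold and 9.15-fold. Vwf read 6.84 in T23 and 6.75 in T1525, just above the background threshold of 6.69, so background limits its fold too. Of 7 mast cell genes, 2 fell over all genes and 3 when adjusted over the list alone, with a median of -0.88 (camera adjusted p = 0.00348; adjusted p = 0.359 with an estimated correlation). The mast cell median was -1.55 without T23, -0.41 with no filter on dim probes, -1.48 with the threshold on at least 2 arrays and -2.09 with a stricter tail. Kit, the stem cell factor receptor, was at least 7.97-fold lower and Mcpt4, a mast cell chymase, at least 2.16-fold lower.

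Of 13 neuroendocrine genes, 4 fell over all genes and 4 when adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.0481; adjusted p = 0.359 with an estimated correlation). Syp, synaptophysin of synaptic vesicles, was at least 7.03-fold lower (adjusted p = 0.0191), and Stmn2 was at least 6.87-fold lower. Chga, chromogranin A, read between 6.32 and 6.85 on all 4 arrays. Sox2 and Foxa2, also of this list, went the other way in T1525, by at least 3.71 and at least 3.46 on the log2 scale against normal prostate. The list's call ended in 6 of 12 alternatives: with median scaling (median -0.51, adjusted p = 0.0916), cyclic loess (-0.40, adjusted p = 0.0931) and a looser background tail (-0.02, adjusted p = 0.0624), and without T23 (median -0.996, adjusted p = 0.185), T1525 (median -0.91, adjusted p = 0.0881) or normal 2 (median -0.25, adjusted p = 0.0793). With no filter on dim probes the list was called but its median was 0.03 (adjusted p = 0.0446), and it was -0.81 with the threshold on at least 2 arrays and -0.70 with a stricter tail. Its adjusted p lay between 0.00867 and 0.185 over these alternatives.

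Other lists had few or no genes past the threshold in the class comparison. With 2 arrays in each class, a count of 0 does not show that no gene changed. In the glycolysis and hypoxia list, 0 of 17 genes changed over all genes and 0 when adjusted over the list alone; the median was 0.77 (camera adjusted p = 0.00499; adjusted p = 0.461 with an estimated correlation), and Tpi1, triosephosphate isomerase, missed the threshold at 1.33 (adjusted p = 0.0557). Without T1525 the median of this list was 0.42. With all arrays, its median difference from normal prostate was 0.38 in T23 and 0.91 in T1525. In the MHC class I list, 0 of 11 changed by either adjustment, with a median of -0.63 (camera adjusted p = 0.0226; adjusted p = 0.603 with an estimated correlation), and that call ended without T1525 (median -0.40, adjusted p = 0.255) or normal 2 (median -0.69, adjusted p = 0.126), while the median was -1.23 without T23 and -1.03 without normal 1. Its adjusted p lay between 0.000677 and 0.255 over 12 alternatives. In the p53 pathway list, 0 of 14 changed by either adjustment (median 0.26, camera adjusted p = 0.4), and in the interferon list 0 of 13 (median -0.19, camera adjusted p = 0.4). In the stem-like list of 12 genes, Bmi1, a Polycomb protein, rose 5.03-fold (adjusted p = 0.0259) and Psca, prostate stem cell antigen, fell 57.3-fold (adjusted p = 0.0397; 136-fold without normal 1 and 24.2-fold without normal 2), with 3 higher and 2 lower when adjusted over the list alone (median -0.20, camera adjusted p = 0.972; fry gave the opposite direction, adjusted p = 0.369). Rb1, the retinoblastoma tumor suppressor, read 9.02 ± 0.90 (SD, n = 2) in the lines and 8.55 ± 0.24 (SD, n = 2) in normal prostate (limma, adjusted p = 0.555).

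With each value at or below background set to the threshold, the medians were 3.13 for the cell cycle list, -5.12 for prostate secretory, -6.58 for seminal vesicle, -1.26 for luminal regulators, -1.65 for epithelial, -1.87 for basal, -4.41 for smooth muscle, -3.80 for skeletal muscle, -4.97 for adipose, -2.44 for blood, -3.89 for leukocyte, -2.87 for endothelial and -0.63 for mast cell genes. They were -0.06 for neuroendocrine, 0.24 for mesenchymal, -0.36 for fibroblast and matrix, -0.23 for protease, 0.15 for p53, -0.09 for interferon, 0.74 for glycolysis and hypoxia and -0.35 for stem-like genes, and those of the MHC class I and the mast cell attracting lists did not move. Of 23 lists, 16 passed camera, 0 of them with an estimated correlation, and 10 passed fry, which asks whether the genes of a list move one way and does not compare them with other genes. Camera with an estimated correlation rests on 2 residual degrees of freedom. The smooth muscle list, with an estimated correlation of -0.036 against the preset 0.01, went from camera adjusted p = 3.35e-09 to 0.242. A failure there therefore says little on whether the genes of a list shifted.

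In the epithelial adhesion and keratin list, 0 of 23 genes changed by either adjustment, with a median of -1.90 (camera adjusted p = 0.0545; adjusted p = 0.789 with an estimated correlation). Camera called this list in 4 of 12 alternatives. These were no filter on dim probes (camera adjusted p = 0.0253), a looser background tail (camera adjusted p = 0.0493), the mean of a gene's probes (camera adjusted p = 0.0449) and leaving out T1525, where the median was -4.39. In the mesenchymal list of 21 genes, 1 rose over all genes and 0 when adjusted over the list alone (median 0.66, camera adjusted p = 0.5). The call differed in 1 of 12 alternatives, without T1525, where the median was 1.98. Against normal prostate the median of this list was 1.86 in T23 and -0.87 in T1525, so the lines lay on opposite sides. With values at background set to the threshold, this median was 1.86 in T23 and -0.32 in T1525. In the fibroblast and matrix list of 17 genes, 2 fell by either adjustment, Lum at least 6.14-fold (10.5-fold without normal 1 and 3.59-fold without normal 2) and Gsn at least 10.3-fold lower, with a median of -0.74 (camera adjusted p = 0.05; adjusted p = 0.726 with an estimated correlation). Without T1525 that median was 1.34 and without normal 2 it was 0.19, and the call ended in both cases; it was -2.83 without T23 and -1.67 without normal 1. The call of this list ended in 7 of 12 alternatives, with adjusted p between 1.66e-05 and 0.597. In the protease list of 20 genes, Mmp7, matrilysin, was at least 20.2-fold lower (adjusted p = 0.0187) and Mmp23 at least 7.19-fold lower, with 1 gene higher; 2 were higher and 4 lower when adjusted over the list alone (median -0.44, camera adjusted p = 0.4). Without T23 its median was -1.26 and camera called it, with adjusted p between 0.0245 and 0.91 over 12 alternatives. Mmp9, the gelatinase B gene, read 8.84 in T23, 7.01 in T1525, 9.04 in normal 1 and 8.98 in normal 2 (lines against normal, limma, adjusted p = 0.34). In the list of 13 mast cell attracting and growth factors, Il33 fell 14.4-fold (adjusted p = 0.0486; 26.0-fold without normal 1 and 7.96-fold without normal 2), with 0 when adjusted over the list alone (median -0.12, camera adjusted p = 0.723, between 0.0479 and 0.965 over 12 alternatives); without T23 the median was -0.92 and camera called it.

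Each line was also set against normal prostate. In T23, limma called 4591 probes, 2574 higher and 2017 lower; in T1525 it called 4695, 2708 higher and 1987 lower. Here the spread came from the 2 normal samples alone, the single line being assumed to vary like them. Simulated data with known changes gave 8.93% false calls for T23 and 7.65% for T1525 when variances were drawn from the fitted prior. When each probe kept its fitted variance they gave 24.7% and 24.6%, and all 4 rates were above the nominal level. The simulations changed 200 of 15767 probes, far fewer than were called here. The share of false calls depends on that number, so these rates do not give it for the real calls. Median scaling gave 41.9% higher calls in T23 and 44.2% in T1525, and cyclic loess 42.8% and 43.8%, against 56.1% and 57.7% with the deposited values.

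The cell cycle list rose in full in each line, with 24 of 24 genes called. In T23, 17 of 23 epithelial genes fell and 1 rose; Krt8, a luminal keratin, differed from normal prostate by -7.11 or lower (adjusted p = 0.00507), Cdh1, the epithelial cadherin, by -4.01 or lower (adjusted p = 0.0056) and Rab25 by -6.52 or lower (adjusted p = 0.00491). In T1525, 2 of the 23 rose and 2 fell; Krt8 differed by 0.32 (adjusted p = 0.476) and Cdh1 by 0.25 (adjusted p = 0.42), while Cldn3 fell by 3.25 (adjusted p = 0.01). In T23, 12 of 21 mesenchymal genes rose and 0 fell, among them S100a4 (log2 difference 4.77, adjusted p = 0.0056), Tnc, the matrix protein tenascin C (3.17, adjusted p = 0.0366), and Sparc (2.10, adjusted p = 0.0489). In T1525, 3 rose and 5 fell, with Zeb1, a repressor of epithelial genes, down (-3.73 or lower, adjusted p = 0.00523) and Cd44, a hyaluronan receptor, up (at least 3.94, adjusted p = 0.0156). Of 17 fibroblast and matrix genes, 10 fell in T1525 and 1 rose, whereas 4 rose and 3 fell in T23.

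T1525 had higher Sox2 (log2 difference at least 3.71, adjusted p = 0.00523), Foxa2 (at least 3.46, adjusted p = 0.00508), Kitl, the ligand of Kit (at least 1.33, adjusted p = 0.014), and Cdkn2a, the gene of p16 and p19ARF (at least 4.35, adjusted p = 0.00517). In T23 these genes did not pass. T23 had higher Csf1, the macrophage growth factor (4.32, adjusted p = 0.0166), and T1525 had lower Cxcl12 (-4.99 or lower, adjusted p = 0.00505) and B2m, the light chain of MHC class I (-4.85, adjusted p = 0.00505); B2m also fell in T23, by 1.44 (adjusted p = 0.0215). Mmp9 fell in T1525 (-1.99, adjusted p = 0.0116), and its difference in T23 was -0.17 (adjusted p = 0.572).

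Both lines were called higher at 1466 probes and lower at 1206, and in opposite directions at 184. With unchanged groups against the same 2 normal samples, simulation gave means of 1.7, 1.44 and 0.46 probes, and independent lists of these lengths would share 442 and 254. The simulation held no changed probe and so made few calls of any kind. Its means therefore do not measure what the shared samples add to the overlap of the real calls. The changes of the 2 lines correlated across probes with r = 0.672, against 0.333 in the simulation, with a covariance of 1.44 against 0.0356; part of the overlap may come from the shared normal samples, which are too few to split.

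The lines were then set against each other, with 1 array each and therefore no test. Krt8 read 5.98 in T23 and 14.12 in T1525, at least 172-fold apart. Lox, lysyl oxidase, which crosslinks collagen, read 14.80 in T23 and 6.42 in T1525, at least 276-fold apart. By a log2 difference of at least 2, 638 probes were higher in T23 and 535 in T1525, 1173 in all, against 217 between the 2 normal samples, of which 189 were higher in normal 2.

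As measured, the 10 largest differences toward T23 were in Lox, Acta2, Serpinh1, Serpinf1, Col6a1, Axl, Lgals1, Mgp, Aebp1 and Epb41l3. Acta2, the smooth muscle and myofibroblast actin, was at least 261-fold higher in T23, Serpinh1, the collagen chaperone, at least 226-fold, and Axl, a receptor tyrosine kinase, 204-fold. The 10 largest toward T1525 were in Sox21, Krt8, Krt14, Igf2, Aldh3a1, Foxq1, Grb7, Krt7, Rab25 and Gpx2. Sox21 was at least 251-fold higher in T1525, Igf2, an imprinted growth factor, 189-fold, and Krt14, a basal keratin, at least 130-fold. With values at background set to the threshold, 10 of the 10 toward T23 and 9 of the 10 toward T1525, without Grb7, stayed among the 10 largest.

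**Figure D2:**
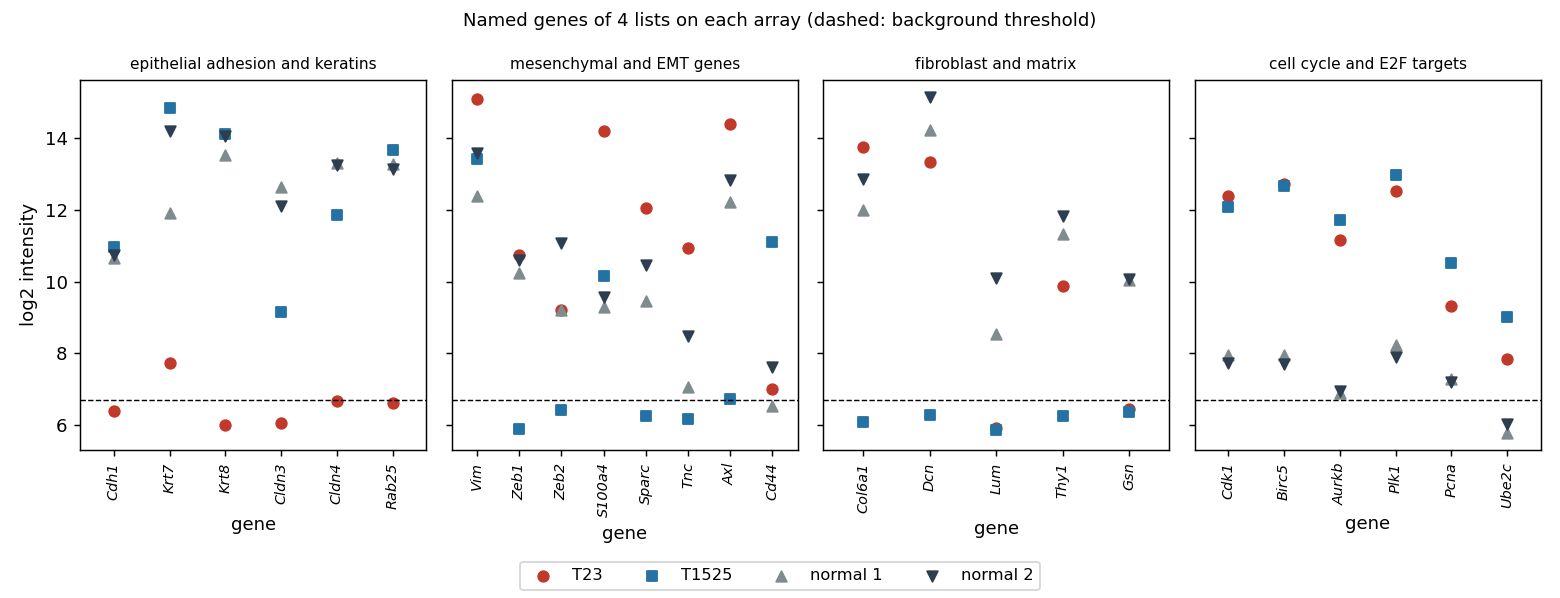
Log2 intensity (vertical axis) of the named genes of 4 lists (horizontal axis) on each of the 4 arrays, 1 point per array, with the background threshold of 6.69 dashed. Krt8 in T23 (5.98) and Col6a1 in T1525 (6.08) lie below the threshold, and Birc5 lies at 12.73 and 12.67 in the lines against 7.95 and 7.69 in the normal samples.

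By list, 9 of 23 had a median difference between the lines outside the central range of 10000 random lists of like expression, but so had 12 between the 2 normal samples, 6 of them the same lists. Lying outside that range therefore does not set the lines apart. Normal 1 minus normal 2 had medians of 0.11 for the epithelial list, -0.66 for basal, -1.09 for fibroblast and matrix, -0.60 for mesenchymal, -0.75 for mast cell attracting and growth factors, -0.59 for protease, -0.65 for MHC class I, -0.04 for glycolysis and hypoxia and -0.03 for stem-like genes. In each of the 9 the lines differed by more than the normal samples did. The epithelial list had a median of -4.58 for T23 minus T1525, with 18 of 23 genes higher in T1525 by at least 2 and 5 above background in T23 against 23 in T1525. The basal list had -1.71, although Trp63 was higher in T23 (8.24 against 6.06). The fibroblast and matrix list had 3.66, with 12 of 17 higher in T23 by at least 2 and Igf1 the 1 gene higher in T1525, a name chosen after its values were seen. The mesenchymal list had 2.98, with 14 of 21 higher in T23 and 1, Cd44, in T1525. Dcn, the proteoglycan decorin, was at least 101-fold higher in T23 and Cxcl12 at least 41.7-fold. With values at background set to the threshold, the medians of these lists were -3.92 for epithelial, -1.34 for basal, 3.18 for fibroblast and matrix and 2.91 for mesenchymal genes.

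The mast cell attracting and growth factor list had a median of 2.23, with Csf1 40.6-fold and Cxcl1 29.3-fold higher in T23, whereas Kitl was at least 2.51-fold higher in T1525. The protease list had 0.81, with Mmp2, gelatinase A, at least 49.3-fold and Timp3 23.7-fold higher in T23, and Mmp9 3.54-fold. The MHC class I list had 0.98, with B2m 10.7-fold higher in T23 and Psmb8, an immunoproteasome subunit, at least 6.04-fold. The glycolysis and hypoxia list had -0.66, with Pfkp 5.41-fold higher in T1525 and Adm, adrenomedullin, 5.38-fold higher in T23. The stem-like list had -0.71, with Prom1 at least 68.2-fold higher in T1525. With values at background set to the threshold, the medians were 1.87 for mast cell attracting and growth factors, 0.78 for protease, 0.98 for MHC class I, -0.42 for glycolysis and hypoxia and -0.46 for stem-like genes.

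The medians of the other lists were -0.40 for the cell cycle list, 0.13 for p53 targets, 0.37 for interferon genes, -0.39 for neuroendocrine genes, -0.16 for luminal regulators, 0.01 for prostate secretory and 0.26 for seminal vesicle genes, 0.28 for mast cell genes, 0.08 for smooth muscle, 0.03 for endothelium, 0.02 for leukocytes, -0.13 for skeletal muscle, -0.18 for adipose and 0.11 for blood. Within the smooth muscle list Acta2 and Tpm2 were at least 261-fold and at least 80.7-fold higher in T23, while Myh11 lay at background in both lines.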

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

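The tests of stromal RNA and of a mixture with epithelial cells were chosen after the results were seen. Of 147 named genes, 31 read above both normal samples in one line and below both in the other, and 29 did so with values at background set to the threshold, 17 with T23 above and 12 with T1525 above. The other 2 were Chga and Kdr, which lay at background in T23 and in both normal samples. Of the 31, 10 were called by limma in both lines. The difference between the lines was not tested for any of them, since each line has 1 array. Among all genes, 155 were called in opposite directions, 97 higher in T23 and lower in T1525 and 58 the reverse.

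On the log2 scale, T23 exceeded T1525 by 7.67 in Axl, 7.66 in Lgals1, 5.34 in Csf1 and 3.42 in Ifit2. Where T1525 was at background the difference was at least 8.11 in Lox, 7.82 in Serpinh1, 7.68 in Serpinf1, 7.60 in Mgp, 7.38 in Epb41l3, 7.29 in Aebp1, 7.07 in Col6a1, 5.38 in Cxcl12, 5.36 in Sparc, 4.24 in Tnc, 4.04 in Zeb1, 2.64 in Ifit3 and 2.59 in Psmb8. T23 minus T1525 was -7.56 in Igf2, -7.14 in Krt7 and -6.99 in Gpx2. Where T23 was at background, the difference was at least as far below 0 as -7.43 in Krt8, -7.06 in Foxq1, -7.03 in Krt14, -6.97 in Rab25, -6.83 in Aldh3a1, -6.36 in Grb7, -5.93 in Lamb3, -4.27 in Cdh1, -4.02 in Cdkn2b, -1 in Kdr and -0.15 in Chga.

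In T23, 12 of 21 mesenchymal genes were called higher than normal, and 5 of 23 epithelial genes lay above background. RNA of normal prostate stroma in T23 is argued against, since smooth muscle, endothelial and leukocyte genes differed from normal by medians of -3.27, -2.94 and -3.89 with values at background set to the threshold, against 1.86 for mesenchymal genes, a gap of -4.80 for the nearest of the 3. These medians leave out single genes: 12 of the 41 lay above background in T23, among them 7 of 13 smooth muscle genes. Acta2 read 14.72 in T23 against a mean of 15.68 in normal prostate. Fibroblasts without those other cells stay open, as the median T23 level of the fibroblast and matrix list was 9.87 against 9.31 in normal prostate. The median share of the T1525 intensity over background found in T23 was 0.117% over 23 epithelial genes, although 5 of them had a share of 5% or more. This restates the background level of the same genes. It limits how large a mixture with epithelial cells like T1525 could be, but is not separate evidence against one. Whether T23 came from changed epithelial tumor cells or from stromal cells that grew out may be asked but was not tested.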

How the results depend on the processing

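Normexp correction and the stricter tail were chosen after the data were seen. Without 1 array limma called between 0 and 4823 probes against 1698. It called 0 without either normal sample, where the lone normal sample is assumed to vary like the lines, with 2507 and 2266 probes at an unadjusted p under 0.05; without a line the spread comes from the normal samples alone. With that spread and all arrays the count was 5747, the largest. Under the other alternatives run it lay between 1507 and 1928, and the single-line counts between 3896 and 5740. At a log2 difference of at least 1, 3201 probes differed between the lines against 1173. Of the lists, 16 passed camera, 0 with an estimated correlation and 10 with fry, and between 13 and 17 under the other alternatives. Between the lines, 9 to 11 lists lay outside the random range, with 12 between the normal samples for the values used.

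The fibroblast and matrix list and Sparc turned over without T1525: leaving out 1 array gave list medians between -2.83 and 1.34, and fitted Sparc differences between -3.71 and 2.10, since T23 and T1525 lay on opposite sides of normal. As limma called 0 probes without either normal sample, every called gene followed there lost its call, 60 named genes without normal 1 and 60 without normal 2. This singles out no gene. Under scaling, filter and variance alternatives, Il33, Col17a1, Krt15, Lum and Vwf lost their call under at least 1 of them; the cause was not tested.

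No paired analysis was possible because the labels pair no line with a normal sample. The alternatives without background correction and with the authors' processed values are the setting used and have no value of their own. Slides as a block were not run, since the slides of the samples are not known. With 1 line and 1 normal sample no residual degrees of freedom are left, so the single-line counts have no value without a normal sample. About 51% of the probes lay above background on each array, so falls of dim genes are bounded by the background.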

Other observations

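The tests of chance placement among chromosomes, of ranks within arrays, of lost non-epithelial cells, and of neighbouring genes, and the Hox genes, were chosen after the results were seen. Hox genes, which set position along the body axis, were counted by cluster in the fits of single lines. Of 7 measured Hoxa genes, 5 rose in T1525 and 2 in T23 by limma; Hoxa5, Hoxa7 and Hoxa9 differed from normal prostate by 2.89, 2.59 and 2.84 in T1525. Of 8 Hoxb genes, 7 fell in T1525 and 5 in T23, with Hoxb7 at -4.60 or lower in T1525. Of 7 Hoxd genes, 5 fell in T1525 and 4 in T23; Hoxd10 (-2.74 or lower, limma adjusted p = 0.0174) and Hoxd4 (-3.58 or lower, limma adjusted p = 0.0304) fell in the class comparison. Of 7 Hoxc genes, Hoxc6 and Hoxc9 rose in T23, by 2.33 and 1.83, and 0 changed in T1525. With values at background set to the threshold, T23 lay above T1525 in 19 of the 29.

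Cdkn2a and its neighbour Cdkn2b were at background in T23 and above it in T1525, names chosen after their values were seen except where the rule gave them. Cdkn2a read 6.68 in T23, 11.13 in T1525, 6.56 in normal 1 and 6.86 in normal 2, so T23 lay between the normal samples there. Cdkn2b, a cell cycle inhibitor, read 6.64, 10.71, 8.79 and 10.08 and was lower in T23 than in normal prostate (limma, adjusted p = 0.0406). The neighbour Mtap, an enzyme of methionine salvage, rose in T23 by 2.72 (limma, adjusted p = 0.00956).

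Relative to all 4495 genes used, the median of T1525 minus normal was 0.91 over 148 genes of chromosome 12 and 0.32 over chromosome 13, while T23 minus normal was called at -0.37 for chromosome 12, 0.32 for chromosome 3 and -0.23 for chromosome 7, so a value of the size of chromosome 13 was not particular to T1525. Chance placement of the chromosome 12 value is argued against by the adjusted permutation p of 2e-04, the smallest p before adjustment being 1e-05; neighbouring genes are not independent, so this p may be too small. The deposited values were as after quantile normalization, which keeps ranks on each array. A change of scale that keeps ranks is argued against for chromosome 12 by a median rise in rank of 4.11% of the probes relative to all genes. With nearly the same sorted values in each column, this restates the rise in intensity and is no second line of evidence for it. The lowest median of 0.905 over 3 other scalings starts from values already normalized and decides nothing. A step of the authors' normalization or background that changed ranks therefore stays open. Higher gene dosage over the whole of chromosome 12 is a candidate explanation, as the medians of all 4 runs of genes along it reached the set bound of 0.3. They were 0.98, 0.93, 0.97 and 0.359, so the rise was not even and the last run rose least. Over the whole of chromosome 13 higher dosage is argued against by a lowest run of -0.0236, the first run being at 0.80. DNA was not measured, and of 60 chromosome values tested 13 were called.

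Prostate secretory genes were low in both lines. Loss of non-epithelial cells in culture is argued against in T1525, since there the secretory median fell further than the epithelial median, by -5.75 on the log2 scale; in T23 the same gap was -1.35, with the epithelial list itself at background, and the explanation stays open there. The median rank changed by -55.6% of the probes in T23 and -56.2% in T1525, which argues against a change of scale on each array that keeps ranks. With nearly the same sorted values in each column, a fall in intensity is a fall in rank. The ranks are therefore no second line of evidence for the fall. The highest secretory median of -5.26 over 3 other scalings starts from values already normalized and decides nothing, so a step of the authors' normalization or background that changed ranks stays open. Culture itself, age and the tumor stay open and were not tested.

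Neighbouring genes at background in a line, as a lost stretch of DNA would leave, did not pass a permutation test of their number. T23 had 5 such pairs among 108 genes at background, against a permuted mean of 2.89 (one-sided permutation p = 0.167), and T1525 had 5 among 103, against 2.65 (one-sided permutation p = 0.13). That permutation test had no check on data with a known loss. The test of chromosome medians was checked on the measured T1525 minus normal values with chromosome labels shuffled over genes. There, 0.5 added to the genes labelled chromosome 12 was called in 19 of 20 rounds and 0 added in 0 of 20. The shuffling removes any dependence between neighbouring genes, so this check does not cover it.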
